A study of Homo sapiens with 16 samples.

How the data were processed

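RNA was measured by sequencing in NCI-H1944 cells, a human lung adenocarcinoma line, in 16 libraries. Per the labels, there were 4 genotypes. SCR is the control labelled wild type, STING and MAVS are lines made with a guide against 1 of these genes, and DKO is a double knockout line. Each genotype was sampled with 2 replicates after MPS1i and 2 after DMSO. Per the labels' protocols, MPS1i is BAY-1217389, an inhibitor of the mitotic kinase MPS1 (gene TTK), given at 100 nM for 48 h and removed 24 h before harvest. Also per the labels' protocols, poly(A) RNA was enriched, ribosomal RNA was blocked, libraries were made with a stranded QIAseq kit, and they were converted for DNBSEQ sequencing.

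The deposited values are raw counts per gene, with 1 column per library, and no normalization was applied to them per the file headers and the submitters' processing notes. Per the submitters' processing notes, reads were trimmed (Trim Galore, cutadapt and Trimmomatic are named), aligned with STAR to GRCh38/hg38 and counted with featureCounts. The notes give no versions, no strand setting and no handling of reads that map to more than 1 place. The values were checked to be whole numbers. Gene IDs, symbols, types and coordinates were taken from the deposited table, which holds 60612 genes, 44 of them second copies from the Y pseudoautosomal region, and no gene of the mitochondrial genome. RIGI is listed there under its older symbol DDX58, which is used below. All 16 columns matched a library by name. Near-identical genes (IFNL2 and IFNL3, histone genes, pseudogenes and readthrough genes) may share reads. Antisense genes may hold reads of their partners, since the strand setting is not stated. As poly(A) RNA was enriched, values of replication histone genes and U2 copies cover only the transcripts captured that way.

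Total counts per library ran from 19893784 to 49769938. At these depths, a gene with 0 counts in a library may still be present at up to 3 counts in that library. Folds against a group with 0 counts in both libraries are given as "at least", from that floor per library. Such floors cover counting error only. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries. Residuals of replicates with the same number were compared over 28 pairs of groups. Their correlations ran from -0.4 to 0.3 with a median of 0, so replicates were not treated as paired, and a fit with the replicate number as a block was kept as an alternative.

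Fits used R 4.3.3. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 17950 genes, 14113 of them protein coding. The kept genes hold at least 99.93% of each library's counts. edgeR 4.0.16 was used with TMM normalization, robust dispersion estimates and the quasi-likelihood F-test (two-sided) on a model with 1 mean per group, which leaves 8 residual degrees of freedom. Values of p were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Each adjusted p for a gene comes from this test. There were 15 contrasts: the effect of MPS1i in each genotype, each knockout-labelled line against SCR under DMSO and under MPS1i, and 5 differences between treatment effects (interaction terms). CPM, the counts scaled to a common library total, were computed from the TMM-scaled totals and carry the standard deviation (SD) of 2 libraries. The number after ± beside a log2 fold change is the standard error implied by the quasi-likelihood F statistic. It is the absolute log2 fold change divided by the square root of F. Where a group is near 0 counts, it may not hold.

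Named genes follow a rule. It takes 15 fixed genes, the 6 largest rises and the 6 largest falls of each contrast among called genes with a mean of at least 1 CPM, and up to 4 members of each list with the smallest adjusted p. For genotype and treatment effects, the libraries of the 2 groups had to be apart for a largest rise or fall, and XIST and Y-linked genes were left out. Where a list had no called member, its 2 members with the highest mean CPM could be named. Across contrasts, the 6 genes with the smallest larger adjusted p were taken. Where the text singles out a gene for other reasons, it says so.

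The gene lists were written from general knowledge. They cover interferon response, interferon and chemokine genes, NF-kB and inflammation, nucleic acid sensing, antigen presentation, p53 targets, mitosis, DNA replication, replication histones, cholesterol synthesis, ATF4 and endoplasmic reticulum stress, NRF2 targets, lysosome, matrix and TGF-beta, lung epithelium, immune cells, stromal and endothelial cells, and the mitochondrial genome. Of 18 lists, 17 had at least 3 tested members. The mitochondrial list could not be tested, as the table holds none of its genes. The nucleic acid sensing list shares 2 genes with the interferon list. SLC7A11 is in both the ATF4 and the NRF2 list, and other overlaps between lists are not given. Lists were tested against all other genes with camera (limma 3.58.1, voom weights, preset correlation 0.01, two-sided) and adjusted over the 17 lists of a contrast. Camera was repeated with a correlation estimated for each list. A list is said to have risen or fallen only where both forms called it. For medians with genes at their bound, a group at 0 counts is set to 3 counts per library, and a gene at 0 in both groups of a treatment effect counts as no change. Members called against the direction of a called list were fitted again under every alternative, and where several left-out libraries ended such a call, the report gives 1 of them.

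Lists, contrasts, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were another normalization (edgeR's RLE), another tool (DESeq2 1.42.0), no filter on low counts, a filter of at least 1 CPM in at least 2 libraries together with a mean of at least 1, fits on only the compared groups, the replicate block, leaving out each library in turn, the estimated correlation, and the rotation test fry. Thinning all libraries to the smallest total was added after seeing the data. With 1 library left out, the lone library of a group is assumed to vary like the other groups.

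The fit was tested on simulated counts drawn from the means and library sizes of these samples with 200 genes outside the lists changed and the 27 tested lysosome genes raised by 0.5 on the log2 scale. The shares below are of the 200, and calls of either set count as true. The 200 had a mean of at least 1 CPM, so the shares do not cover scarcer genes. Far fewer genes were changed than were called in SCR, so a change of that extent was not tested. For the treatment effect in SCR (17448 genes), 90% of genes changed by 1 on the log2 scale and 77% of those changed by 0.5 were recovered, with 15 false among 206 calls. For the difference between DKO and SCR, the shares were 78% and 54%, with 5 false among 156 calls. In both, camera called the list that held changed genes and no other list, with the preset correlation. The simulated genes were drawn independently of each other, so this does not test whether the preset correlation is too low. In a contrast simulated without change (treatment effect in DKO, edgeR), no gene was called.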

Results

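Gene expression was measured by RNA sequencing in NCI-H1944 lung adenocarcinoma cells. They carried a control guide (SCR, labelled wild type), a guide against STING or a guide against MAVS, or were labelled as a double knockout (DKO). STING relays the detection of cytosolic DNA by cGAS, and MAVS relays the detection of cytosolic RNA by RIG-I and MDA5. Both pathways turn on interferons. Each genotype was sampled after a pulse of the MPS1 inhibitor BAY-1217389 (MPS1i) and after DMSO, with 2 libraries in each of the 8 groups, 16 in all. MPS1 is the kinase of the spindle checkpoint, so its inhibition disturbs chromosome segregation. Per the series' description, the question is which expression changes after the pulse depend on STING, on MAVS or on both.

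Total counts per library were 49769938 and 35292086 in SCR DMSO, 36769058 and 45854868 in SCR MPS1i, 24036388 and 20247175 in STING DMSO, and 26290514 and 28736653 in STING MPS1i. They were 27610499 and 19893784 in MAVS DMSO, 33611396 and 38165853 in MAVS MPS1i, 25567196 and 35839036 in DKO DMSO, and 33601232 and 20635229 in DKO MPS1i. The 10 most abundant genes held between 5.72% and 6.86% of the counts of a library. The first principal component held 34.7% of the variance and the second 12.6%, and replicates of a group lay close together on the first. On the second, the DKO DMSO replicates stood furthest apart, at -31.4 and -21.8. By chi-square per gene the DKO DMSO replicates differed most (8.72, against 2.69 to 5.62 in other groups). By correlation of log2 CPM the STING DMSO replicates did (0.9793, against 0.9814 in DKO DMSO). Log2 fold changes are given ± their standard error, levels as mean CPM ± SD (n = 2), and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. List medians are medians of members' log2 fold changes, tested with camera. Genes described as the largest rises, falls or losses of a comparison are so among genes with a mean of at least 1 CPM. Fold floors given as at least a value cover counting error only, and the labels do not say whether replicates are separate cultures. Members named because 5 or fewer met a condition were chosen after their values were seen.

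The STING transcript was lower in the lines labelled as STING knockouts, and the MAVS transcript was not lower in the lines labelled as MAVS knockouts. STING1 (ENSG00000184584, chromosome 5, 139475533 to 139482935, GRCh38) stood under DMSO at 8.27 ± 0.0317 CPM (SD, n = 2) in SCR, 3.74 ± 0.0573 in STING-labelled, 10.4 ± 0.517 in MAVS-labelled and 4.86 ± 0.0461 in DKO-labelled cells. Against SCR this is a fall by 1.14 on the log2 scale in STING-labelled cells (adjusted p = 2.1e-07) and by 0.77 in DKO-labelled cells (adjusted p = 4e-06). After MPS1i it stood at 29.0 ± 0.167, 5.94 ± 0.0706, 18.6 ± 1.91 and 4.12 ± 0.122 CPM in the same order. MAVS (ENSG00000088888, chromosome 20, 3846799 to 3876123) stood under DMSO at 186 ± 4.28 CPM in SCR, 206 ± 3.44 in STING-labelled, 195 ± 0.89 in MAVS-labelled and 215 ± 9.83 in DKO-labelled cells. MAVS-labelled cells differed from SCR by 0.07 ± 0.05 (adjusted p = 0.44), and DKO-labelled cells were higher by 0.2 ± 0.04 (adjusted p = 0.00089). Small edits can stop a protein without lowering its transcript, so the MAVS transcript does not check these labels, and the lines are called MAVS-labelled and DKO-labelled throughout. STING1 rose after MPS1i by 1.81 ± 0.09 in SCR, 0.67 ± 0.13 in STING-labelled and 0.84 ± 0.1 in MAVS-labelled cells. Its level thus varies without an edit, so a lower level alone does not settle the STING labels. TTK (ENSG00000112742, chromosome 6, 80003887 to 80042527), which encodes MPS1, fell after MPS1i in all 4 genotypes. It went from 63.8 ± 3.43 to 33.7 ± 3.24 CPM in SCR, from 55.0 ± 0.369 to 30.4 ± 2.43 in STING-labelled, from 61.3 ± 1.09 to 36.6 ± 0.114 in MAVS-labelled and from 66.4 ± 5.66 to 34.8 ± 0.656 in DKO-labelled cells.

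**Figure D1:**
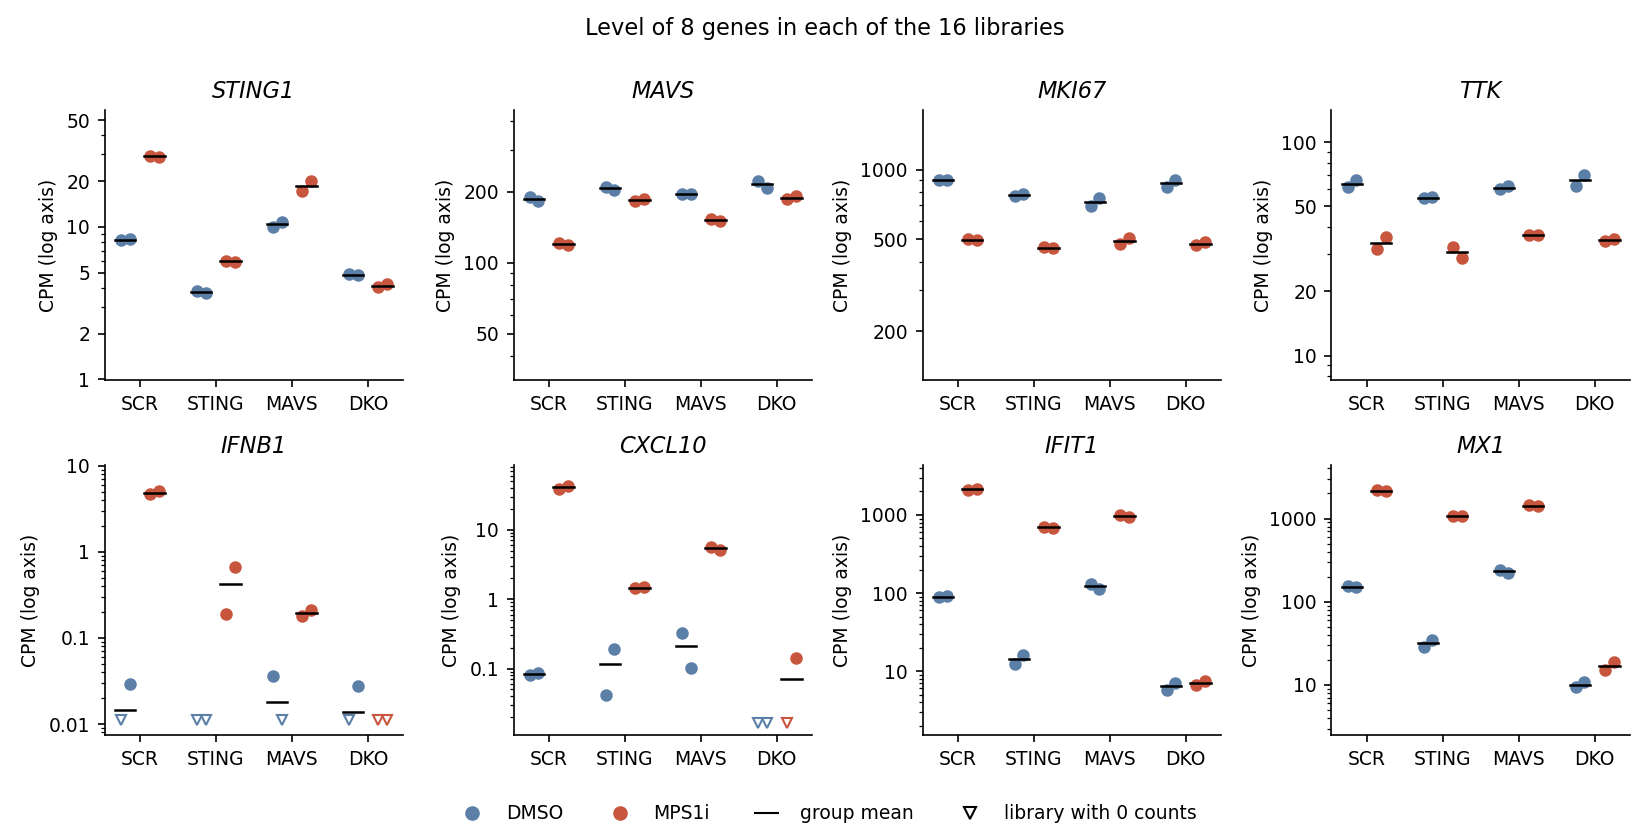
Levels of 8 genes (CPM, log axis) in the 16 libraries, by genotype, with DMSO in blue and MPS1i in red; circles are libraries, black lines are group means and open triangles mark libraries with 0 counts. IFIT1 reached 2128 CPM in SCR after MPS1i and 7.06 CPM in DKO-labelled cells, while MKI67 and TTK were lower after MPS1i in each genotype.

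In SCR cells, the pulse was followed by a large rise of interferon-stimulated, inflammatory and antigen presentation genes and a fall of mitotic genes. All 50 members of the interferon list rose, with a median of 3.22 (adjusted p = 3.6e-53). IFIT1, which binds foreign RNA, went from 89.4 ± 2.34 to 2128 ± 57.2 CPM (log2 fold change 4.57 ± 0.1), and the antiviral GTPase MX1 from 152 ± 5.09 to 2171 ± 24.4 CPM (3.83 ± 0.07). Transcripts of the interferons themselves appeared. IFNL1, a type III interferon, rose from 0.108 ± 0.0101 to 12.3 ± 0.992 CPM, and IFNB1 went from 0 and 1 counts to 165 and 222 counts. Of 11 tested interferon and chemokine genes, 10 rose (median 6.79, adjusted p = 9.7e-09) and IFNE, at 0.91, did not pass. CXCL10, a chemokine that attracts T cells, rose from 0.0839 ± 0.00398 to 40.7 ± 2.58 CPM, CCL5 by 3.59 ± 0.06, the death ligand gene TNFSF10 by 5.24 ± 0.09 and CD274, which encodes PD-L1, by 4.89 ± 0.11.

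Other immune lists moved the same way in SCR cells. All 26 NF-kB members rose (median 1.62, adjusted p = 6.9e-20), among them the cytokines CXCL8 by 4 ± 0.07 and IL6 by 3.7 ± 0.07 and the feedback inhibitor TNFAIP3 by 2.6 ± 0.06. All 20 antigen presentation members rose (median 2.15, adjusted p = 5.6e-21), including HLA-B by 3.59 ± 0.07, B2M by 2.37 ± 0.05 and NLRC5, an activator of MHC class I genes, by 3.43 ± 0.08. In the nucleic acid sensing list 19 of 23 members rose (median 1.49, adjusted p = 1.3e-11). DDX58, which encodes RIG-I, rose by 3.43 ± 0.06, IFIH1, which encodes MDA5, by 3.31 ± 0.07, and STING1 and CGAS by 1.81 ± 0.09 and 1.01 ± 0.08. MAVS was the member that fell, by 0.64 on the log2 scale, and RNF135, DDX41 and RNASEH2A did not pass. The matrix and TGF-beta list also rose, with 21 of 30 members up and 2 down, ITGAV and ITGB6 (median 0.56, adjusted p = 4.2e-07), the ITGB6 call being lost without SCR DMSO replicate 2 (-0.3). The fibronectin gene FN1 rose by 1.42 ± 0.05 and the urokinase receptor gene PLAUR by 1.72 ± 0.07. CD68, a macrophage and lysosome marker of the immune cell list, rose by 2.86 ± 0.07, while that list as a whole had a median of 0.95 (adjusted p = 0.14).

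Mitosis genes and ATF4 targets fell in SCR cells. Of 38 mitosis members, 37 fell (median -1.07, adjusted p = 5e-25) and MAD1L1, at 0.32, did not pass. Topoisomerase TOP2A fell by 1.64 ± 0.05 on the log2 scale, cyclin B1 (CCNB1) by 1.19 ± 0.05 and the proliferation marker MKI67 by 0.85 ± 0.05. Of 28 ATF4 and endoplasmic reticulum stress members, 19 fell and 6 rose (median -0.57, adjusted p = 2.7e-06). PSAT1 and ASNS, which take part in making serine and asparagine, changed by -2.87 ± 0.05 and -2.82 ± 0.06, while PPP1R15A, which restarts translation after stress, rose by 1.58 ± 0.06. CBS, a transsulfuration enzyme, and ACO1, an iron-regulated aconitase, were among the largest falls at -2.94 ± 0.09 and -2.68 ± 0.06. Of 23 replication histone genes 19 fell in these poly(A)-enriched libraries, among them H1-5 at -2.01 ± 0.06 (median -1.28, adjusted p = 5.5e-12). That list's adjusted p = 0.063 with an estimated correlation. DNA replication genes went both ways, with 14 of 37 up and 10 down (median 0.06, adjusted p = 0.91). CCNE2, a cyclin of S phase entry, rose by 1.18 ± 0.11. In all, edgeR called 8983 of 17950 genes, 4670 up and 4313 down, and 1492 of them rose and 537 fell at least 2-fold, in all 2029 (treatment effect in SCR with at least 2-fold change), or 1169 with the 1 CPM filter. With p adjusted over the list alone, the counts given for SCR were the same except 22 rising matrix members and 1 rising histone gene.

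In STING-labelled cells, interferon-stimulated genes rose from a lower start, while inflammatory and antigen presentation genes rose less than in SCR. All 50 interferon members rose (median 3.27, adjusted p = 4.3e-89), with IFIT1 up by 5.62 ± 0.11, from 14.2 ± 2.83 to 693 ± 19.9 CPM, and MX1 by 5.08 ± 0.08, from 31.8 ± 4.14 to 1071 ± 2.63 CPM. IFNL1 reached 0.979 ± 0.036 CPM, at least 7.273-fold higher than under DMSO, where it had 0 counts, and IFNB1 had 5 and 19 counts in the 2 MPS1i libraries and 0 under DMSO. Of 11 interferon and chemokine genes 9 rose (median 3.32, or 2.87 with genes at 0 set to their bound, adjusted p = 2.8e-08), with TNFSF10 up by 3.32 ± 0.1 and CXCL10 at 1.47 ± 0.0283 CPM. IFNE and IL15 did not pass. In the NF-kB list 24 of 26 rose (median 0.77, adjusted p = 4.9e-19), CXCL8 by 2.22 ± 0.08 and IL6 by 1.6 ± 0.07, and NFKB1 and TRAF1 did not pass. Antigen presentation rose with 17 of 20 members (median 1.07, adjusted p = 3.6e-19), B2M by 1.11 ± 0.05 and NLRC5 by 2.28 ± 0.09. TAPBPL, CALR and PDIA3 did not pass. Nucleic acid sensors rose with 16 of 23 members (median 1.29, or 0.67 with genes at their bound, adjusted p = 1.3e-14), DDX58 by 3.46 ± 0.07. MAVS stood at -0.16 ± 0.05 (adjusted p = 0.008), with a call that was lost without STING DMSO replicate 1 (-0.16) and without STING MPS1i replicate 1 (-0.15).

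Mitosis fell in STING-labelled cells with 37 of 38 members (median -0.8, adjusted p = 2.9e-38) and replication histones with 19 of 23 (median -0.84, adjusted p = 3.8e-16). TOP2A changed by -1.11 ± 0.05, MKI67 by -0.76 ± 0.05 and the histone gene H2BC4 by -1.11 ± 0.06. DNA replication fell with 13 of 37 members (median -0.17, adjusted p = 6.2e-05), and CCNE2 and RPA2 rose. ATF4 targets fell with 18 of 28 (median -0.27, adjusted p = 3e-08), ASNS at -1.84 ± 0.06 and the stress kinase homologue TRIB3 at -1.16 ± 0.07, and 4 rose, ATF3 by 0.87 ± 0.1, PPP1R15A by 0.49 ± 0.06, SDF2L1 and CEBPB. Among the largest falls were MIR99AHG, a microRNA host gene, at -2.16 ± 0.21 and the receptor gene TNFRSF9 at -1.75 ± 0.1. The matrix list rose with 20 of 30 (median 0.42, adjusted p = 2.4e-07), CCN1 by 1.08 ± 0.09, and ITGB6 fell. The p53 list rose with 13 of 33 (median 0.19, adjusted p = 0.0014), PLK2 by 0.75 ± 0.05, and ZMAT3 and CCNG1 fell. Some of these opposite calls were lost without 1 library: CCNE2 without STING DMSO replicate 1 (0.31), CEBPB without STING DMSO replicate 2 (0.23), and RPA2 (0.23), SDF2L1 (0.18) and ITGB6 (-0.46) without STING MPS1i replicate 2. Adjusted over the list alone, 25 NF-kB, 17 nucleic acid and 15 p53 members rose, and 16 DNA replication and 19 ATF4 members fell. In all 5269 genes were called, 2778 up and 2491 down, and 3364 without STING MPS1i replicate 2.

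MAVS-labelled cells gave a response of the same groups, with smaller interferon folds than SCR. All 50 interferon members rose (median 2.19, adjusted p = 4.7e-74). IFIT1 rose by 3.01 ± 0.09, from 122 ± 14.3 to 981 ± 42.2 CPM, MX1 by 2.62 ± 0.07 and the antiviral factor TRIM22 by 3.35 ± 0.07. Transcripts of IFNL1 went from 1 and 0 counts to 42 and 64 counts, and IFNB1 stood at 0.194 ± 0.0221 CPM after MPS1i. Of 11 interferon and chemokine genes 9 rose (median 2.99, adjusted p = 4.9e-08), with CCL5 at 2.29 ± 0.06 and TNFSF10 at 2.96 ± 0.09, and IFNE and IL15 did not pass. For IFNB1 the call was lost without MAVS DMSO replicate 1 (adjusted p = 0.073) or 2 (0.18) and without MAVS MPS1i replicate 1 (0.068) or 2 (0.12). All 26 NF-kB members rose (median 1.26, adjusted p = 4.9e-25), CXCL8 by 3.11 ± 0.07 and IL6 by 2.68 ± 0.07. All 20 antigen presentation members rose (median 1.33, adjusted p = 5e-23), HLA-B by 2.26 ± 0.07 and B2M by 1.58 ± 0.05. Nucleic acid sensors rose with 19 of 23 (median 0.81, or 0.72 with genes at their bound, adjusted p = 1.2e-12), and MAVS fell by 0.37 on the log2 scale.

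The mitosis list fell in MAVS-labelled cells with 37 of 38 members (median -0.86, adjusted p = 1.7e-33) and replication histones with 19 of 23 (median -1.07, adjusted p = 2.3e-16), TOP2A at -1.19 ± 0.05 and H1-5 at -1.47 ± 0.06. ATF4 targets fell with 16 of 28 (median -0.42, adjusted p = 2.1e-07), PSAT1 at -1.98 ± 0.05 and ASNS at -1.93 ± 0.06, and ATF3, PPP1R15A, HSP90B1 and SDF2L1 rose. CBS, ACO1 and the folate enzyme gene ALDH1L2 were among the largest falls at -2.21 ± 0.08, -2.04 ± 0.06 and -2.41 ± 0.24. NRF2 targets, which respond to oxidants, fell with 13 of 25 (median -0.17, adjusted p = 2.3e-06), the cystine transporter gene SLC7A11 at -0.7 ± 0.05 and ME1 at -0.51 ± 0.05, and CBR1 rose. SLC7A11 is also a member of the ATF4 list. The matrix list rose with 18 of 30 (median 0.41, adjusted p = 1.2e-07), CCN1 by 1.29 ± 0.08, and ITGAV fell. Of the genes that rose against their list, HSP90B1 lost its call without MAVS DMSO replicate 1 (0.12), CBR1 without MAVS DMSO replicate 2 (0.09) and SDF2L1 without MAVS MPS1i replicate 2 (0.21). The mucin gene MUC5AC rose by 2.44 ± 0.08, as it did in SCR by 2.43 ± 0.07. There were 20 rising matrix members when adjusted over the list alone, and the other counts given for this genotype were the same. There were 6001 called genes, 3074 up and 2927 down.

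In DKO-labelled cells the mitotic fall was present and most of the interferon rise was absent. Mitosis fell with 37 of 38 members (median -0.86, adjusted p = 6.5e-60), MKI67 from 871 ± 44.7 to 478 ± 8.96 CPM and TOP2A by 0.99 ± 0.05 on the log2 scale. IFIT1 stood at 6.37 ± 1.00 CPM under DMSO and 7.06 ± 0.453 after MPS1i (0.12 ± 0.17, adjusted p = 0.73). Of 50 interferon members 14 rose, 2 fell (IFI35 and PARP14) and 34 did not pass, with a median of 0.29 (adjusted p = 2.5e-05). The list's adjusted p = 0.14 with an estimated correlation. IFI35 lost its call without DKO DMSO replicate 1 (-0.3) and PARP14 without DKO MPS1i replicate 1 (-0.13). OAS2 rose by 0.78 ± 0.07, MX1 by 0.72 ± 0.11 and OAS1 by 0.63 ± 0.06. GBP4 had the highest value of the list at 2.25 ± 0.61 (adjusted p = 0.012), from 2 and 3 counts to 12 and 10 counts, with adjusted p = 0.085 without DKO DMSO replicate 2, 0.077 without DKO MPS1i replicate 2, 0.083 with libraries thinned to equal depth and 0.056 with only the compared groups. DDX58 (0.18 ± 0.07, adjusted p = 0.098, or 0.29 and adjusted p = 0.02 without DKO DMSO replicate 2), IFIH1 (-0.03 ± 0.09), CGAS (0.11 ± 0.08) and STING1 (-0.24 ± 0.12) did not pass with all libraries. IFNL1 had 0 counts in all 4 DKO libraries, and IFNB1 had 0 counts in both MPS1i libraries. Among interferon and chemokine genes 9 of 11 did not pass (median 0.24, or 0 with genes at their bound, adjusted p = 0.42). For antigen presentation 16 of 20 did not pass (median 0.03, adjusted p = 0.51), and for nucleic acid sensing 18 of 23 (median 0, adjusted p = 0.44).

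Part of the inflammatory response remained measurable in DKO-labelled cells. In the NF-kB list 13 of 26 rose (median 0.26, adjusted p = 1.6e-07), CXCL8 by 1.1 ± 0.07, CXCL1 by 0.91 ± 0.11 and TNFAIP3 by 0.56 ± 0.06. IL24, a cytokine of the IL-10 family, and the transcription factor gene FOSB were among the largest rises at 2.5 ± 0.23 and 2.02 ± 0.27. The p53 list rose with 13 of 33 (median 0.21, adjusted p = 1.7e-09), PLK2 by 0.59 ± 0.05 and the death receptor gene TNFRSF10B by 0.33 ± 0.04, and CCNG1 fell. DNA replication fell with 29 of 37 (median -0.37, adjusted p = 1.1e-21), MCM4 at -0.51 ± 0.04, and CCNE1 rose. Replication histones fell with 20 of 23 (median -0.76, adjusted p = 1.7e-24). Cholesterol synthesis fell with 11 of 24 (median -0.15, adjusted p = 7.9e-06), INSIG1, a brake on sterol synthesis, at -0.46 ± 0.05. ATF4 targets fell with 14 of 28 (median -0.18, adjusted p = 5.9e-13), the glutathione-degrading enzyme gene CHAC1 at -1.91 ± 0.16 and ASNS at -0.85 ± 0.06, and DNAJB9 rose. The matrix list rose with 11 of 30 (median 0.12, adjusted p = 7e-04), PLAUR by 0.68 ± 0.07, and COL4A1, COL4A2 and ITGB6 fell. Lost without 1 library were the calls of CCNE1 (0.19) and DNAJB9 (0.15), without DKO DMSO replicate 1, of ITGB6 (-0.44), without DKO DMSO replicate 2, and of CCNG1 (-0.16), without DKO MPS1i replicate 1. Adjusted over the list alone, 19 interferon, 15 NF-kB, 19 p53 and 12 matrix members rose, and 33 DNA replication, 22 histone, 13 cholesterol and 19 ATF4 members fell. In all 2648 genes were called, 1173 up and 1475 down, and 197 rose and 58 fell at least 2-fold. The total was 1433 without DKO MPS1i replicate 1, 1682 without DKO MPS1i replicate 2 and 1629 with only the compared groups fitted (treatment effect in DKO), and the 255 genes past 2-fold became 144 without DKO MPS1i replicate 1 and 165 without DKO DMSO replicate 2. For the treatment effect in DKO with at least 2-fold change, the number was 107 with the 1 CPM filter and 88 with DESeq2.

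**Figure D2:**
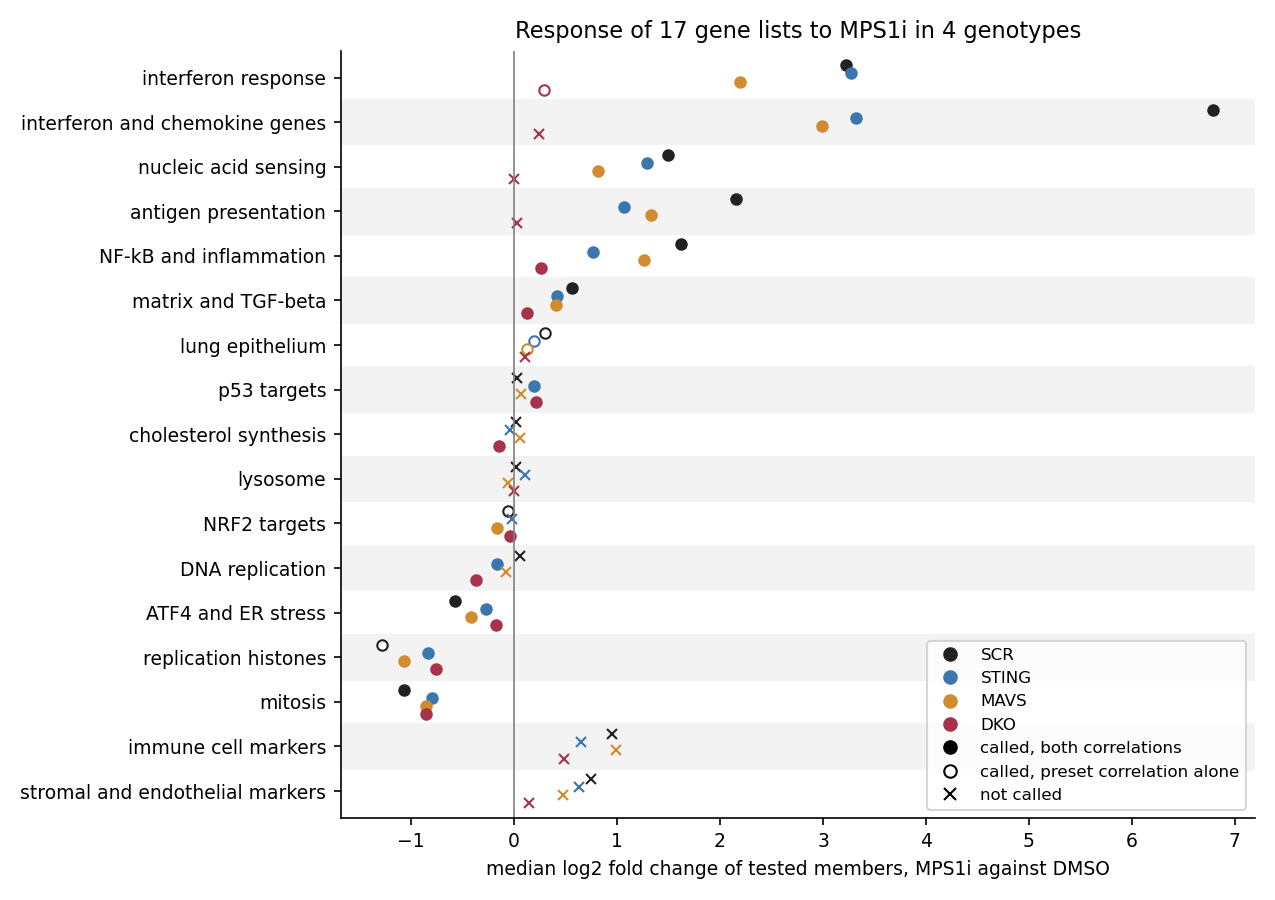
Median log2 fold change after MPS1i of the members of 17 gene lists in the 4 genotypes; filled points were called by camera with both correlation settings, open points with the preset alone, and crosses were not called. The mitosis medians lie between -1.07 and -0.8 in all 4 genotypes, while the interferon median is 3.22 in SCR and 0.29 in DKO-labelled cells.

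Some changes were shared by all 4 genotypes. There were 663 genes called up and 810 called down in all 4. From the 4 counts, 8.1 and 8 would be expected if calls in the 4 genotypes were independent of each other. The rising set was 360 genes without DKO MPS1i replicate 1 and 435 without DKO MPS1i replicate 2. STC1, a secreted glycoprotein, rose by 1.18, 1.23, 1.5 and 1.27 in SCR, STING-labelled, MAVS-labelled and DKO-labelled cells, and CEMIP, a hyaluronan-degrading protein, by 2.08, 2.24, 2.18 and 1.92. CXCL8 rose in all 4 as well, by 4, 2.22, 3.11 and 1.1. The spindle gene ASPM changed by -1.42, -1.11, -1 and -1.14. Of the mitosis list 37 members fell, and of the interferon list 14 rose, in all 4. Of the 1492 genes that rose at least 2-fold in SCR, 51.7% were called up in STING-labelled, 64.9% in MAVS-labelled and 20.2% in DKO-labelled cells, with medians of 0.87, 1.08 and 0.3. These genes were chosen in SCR, so a lower median elsewhere is in part a matter of that choice.

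The question whether the response differed between genotypes was tested directly, as the difference of 2 treatment effects. Against SCR, STING-labelled cells had smaller rises of inflammatory and antigen presentation genes, while interferon-stimulated genes differed in both directions. In the NF-kB list 22 of 26 members had a lower treatment effect (median difference -0.77, adjusted p = 1.8e-20), IL6 by -2.1 ± 0.1, CXCL8 by -1.78 ± 0.11 and TNFAIP3 by -1.56 ± 0.08. All 20 antigen presentation members were lower (median -1.17, adjusted p = 2.1e-26), HLA-B by -1.92 ± 0.11 and B2M by -1.26 ± 0.07. Of 11 interferon and chemokine genes 6 were lower (median -1.92, or -2.97 with genes at their bound, adjusted p = 9.4e-06), CD274 by -2.15 ± 0.23 and TNFSF10 by -1.92 ± 0.15. The interferon list split, with 20 members higher, 16 lower and 14 not passing (median 0.22, adjusted p = 0.12). IFI44L was higher by 1.51 ± 0.08, MX1 by 1.25 ± 0.1 and IFIT1 by 1.05 ± 0.14, and TRIM22 was lower by -1.94 ± 0.11. DDX58 differed by 0.03 ± 0.09 (adjusted p = 0.87). The interferon list was called, upward, without STING DMSO replicate 2 (0.24, adjusted p = 0.04) and with no filter on low counts (0.23, adjusted p = 0.025). NEXN, an actin-binding protein gene, had 1 of the largest losses at -4.85 ± 0.41.

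The other lists that differed in STING-labelled cells were p53 (8 of 33 higher, FAS and PLK2 lower, median 0.19, adjusted p = 0.0033), with ZMAT3 at 1.1 ± 0.08, and ATF4 (14 of 28 higher, with ATF3, PPP1R15A, HSP90B1 and PDIA4 lower, median 0.25, adjusted p = 0.00015), with PSAT1 at 1.25 ± 0.07 and PPP1R15A at -1.09 ± 0.08. For HSP90B1 the call was lost without SCR DMSO replicate 1 (-0.19). DNA replication (9 of 37 lower, 1 higher, median -0.2, adjusted p = 0.00056) and matrix genes (11 of 30 lower, ITGAV higher, median -0.19, adjusted p = 0.00071), with FN1 at -1.03 ± 0.08, had lower treatment effects than in SCR. For matrix genes this is a smaller rise, and for DNA replication a fall in STING-labelled cells beside no call in SCR. The interferon split, adjusted over the list alone, was 22 higher and 18 lower, and 23 NF-kB, 9 p53 and 14 DNA replication members differed in the directions given. In all 3504 genes differed, 1790 higher and 1714 lower.

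MAVS-labelled cells had a smaller interferon response than SCR across the list. Of 50 members 49 were lower (median -1.03, adjusted p = 3.6e-92), TRIM22 by -1.85 ± 0.1, OAS2 by -1.19 ± 0.07 and STAT2, a component of the interferon signalling complex, by -1.03 ± 0.07. RTP4, at -1.03, did not pass. Of 20 antigen presentation members 19 were lower (median -0.89, adjusted p = 3.4e-36), HLA-B by -1.33 ± 0.1 and HLA-E by -1.21 ± 0.07, and PDIA3 did not pass. NF-kB was lower with 10 of 26 (median -0.32, adjusted p = 2.4e-13), IL6 by -1.02 ± 0.09. Nucleic acid sensing was lower with 14 of 23 (median -0.66, or -0.76 with genes at their bound, adjusted p = 9.9e-16), DDX58 by -1.14 ± 0.08, and MAVS was higher. Among interferon and chemokine genes 5 of 11 were lower (median -2.28, adjusted p = 2.1e-11), TNFSF10 by -2.28 ± 0.13, CCL5 by -1.3 ± 0.08, CD274, CXCL11 and CXCL10. The CXCL10 call was lost without MAVS DMSO replicate 1 (-3.19, adjusted p = 0.3). Mitosis fell less than in SCR, with 14 of 38 higher (median 0.27, adjusted p = 1.6e-12), CENPF at 0.61 ± 0.09. ATF4 genes also fell less (10 of 28 higher, PPP1R15A and PDIA4 lower, median 0.18, adjusted p = 2.2e-06), and matrix genes rose less (8 of 30 lower, median -0.17, adjusted p = 0.00033). PDIA4 lost its call without SCR MPS1i replicate 1 (-0.21). When adjusted over the list alone, 50 interferon, 20 antigen presentation, 13 NF-kB, 17 nucleic acid, 6 interferon and chemokine, 22 mitosis, 13 ATF4 and 9 matrix members differed in the directions given. In all 1336 genes differed, 524 higher and 812 lower, and 851 without MAVS DMSO replicate 1.

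The DKO-labelled cells differed most from SCR. All 50 interferon members had a lower treatment effect (median -3.09, adjusted p = 9.8e-60), TRIM22 by -4.81 ± 0.11, IFIT1 by -4.46 ± 0.2 and MX1 by -3.12 ± 0.13. All 20 antigen presentation members were lower (median -2.09, adjusted p = 8.2e-30), HLA-B by -3.34 ± 0.1, as were 24 of 26 NF-kB members (median -1.31, adjusted p = 8.3e-24), IL6 by -3.44 ± 0.09, and 17 of 23 nucleic acid sensing members (median -1.48, adjusted p = 8.6e-16). IL1B and BCL3 did not pass in the NF-kB list, and MAVS was higher in the nucleic acid list. Interferon and chemokine genes had a median of -5, or -6.52 with the 5 genes at 0 in DKO-labelled cells at their bound, with 7 of 11 lower (adjusted p = 8.8e-09), TNFSF10 by -5 ± 0.17. MKI67 (-0.01 ± 0.07, adjusted p = 0.93) and TTK (-0.02 ± 0.1, adjusted p = 0.92) did not differ by more than their error. These genes do not stand for the mitosis list, as TOP2A changed by -1.64 in SCR and -0.99 in DKO-labelled cells. The difference of that list was called with the preset correlation alone, as given below. ACO1 and CBS, which fell in SCR, were higher by 2.63 ± 0.08 and 2.24 ± 0.12. DNA replication was lower with 24 of 37 and higher with 1 (median -0.36, adjusted p = 8.3e-08), MCM4 at -0.68 ± 0.06, and so were cholesterol synthesis with 10 of 24 (median -0.21, adjusted p = 0.0031), HMGCS1 at -1.29 ± 0.06 and 5 members higher (PMVK, EBP, TM7SF2, FDPS and DHCR7), and matrix genes with 16 of 30 (median -0.47, adjusted p = 2e-06), FN1 at -1.31 ± 0.07 and MMP2, ITGAV and TGFBR1 higher. The p53 list was higher with 11 of 33 (median 0.25, adjusted p = 0.0011), ZMAT3 at 1.47 ± 0.08, and FAS and PLK2 were lower, at -0.73 ± 0.08 and -0.48 ± 0.07. Without DKO MPS1i replicate 1 the calls of TM7SF2 (0.41), FDPS (0.22) and TGFBR1 (0.2) were lost, and without DKO MPS1i replicate 2 that of DHCR7 (0.2). With p adjusted over the list alone, 25 NF-kB, 18 nucleic acid and 18 matrix members were lower and the other counts were the same. In all 5021 genes differed, 2415 higher and 2606 lower.

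Against the STING-labelled and the MAVS-labelled line, the interferon response of DKO-labelled cells was smaller too. Compared with STING-labelled cells, 48 of 50 interferon members were lower (median -2.98, adjusted p = 2.1e-146), IFIT1 by -5.5 ± 0.21 and OAS2 by -3.94 ± 0.09, and RSAD2 and GBP4 did not pass. Antigen presentation was lower with 18 of 20 (median -1.12, adjusted p = 3.8e-34), NF-kB with 11 of 26 (median -0.47, adjusted p = 2.8e-19), IL6 at -1.34 ± 0.09, and nucleic acid sensing with 12 of 23 (median -1.17, or -0.85 with genes at their bound, adjusted p = 2.3e-28), DDX58 at -3.28 ± 0.1. CCL5, TNFSF10 and CD274 were lower among interferon and chemokine genes (median -2.16, or -2.59 with genes at their bound, adjusted p = 6.5e-10). DNA replication (median -0.2, adjusted p = 7.9e-06), cholesterol synthesis (median -0.12, adjusted p = 7.1e-05) and matrix genes (median -0.24, adjusted p = 1.5e-05) were lower with 5, 7 and 7 members, MCM4 at -0.44 ± 0.06, HMGCS1 at -0.54 ± 0.06 and THBS1 at -0.5 ± 0.08. The mitosis list had a median of 0.02 (adjusted p = 1). Adjusted over the list alone, 49 interferon, 19 NF-kB, 14 nucleic acid, 6 interferon and chemokine, 7 DNA replication, 8 cholesterol and 8 matrix members were lower. In all 848 genes differed, 279 higher and 569 lower, and 535 without DKO MPS1i replicate 1, 546 without STING DMSO replicate 2 and 564 without STING MPS1i replicate 2.

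Compared with MAVS-labelled cells, 47 of 50 interferon members were lower in DKO-labelled cells (median -1.91, adjusted p = 1.4e-78), MX1 by -1.9 ± 0.13 and IFIT1 by -2.89 ± 0.19, and RSAD2, IRF9 and GBP4 did not pass. NF-kB was lower with 22 of 26 (median -0.99, adjusted p = 7.1e-30), IL6 by -2.42 ± 0.09 and CXCL8 by -2.01 ± 0.1, antigen presentation with 19 of 20 (median -1.28, adjusted p = 5e-34) and nucleic acid sensing with 14 of 23 (median -0.99, or -0.81 with genes at their bound, adjusted p = 1.3e-18). CCL5, TNFSF10 and CD274 were lower among interferon and chemokine genes (median -2.72, or -2.99 with genes at their bound, adjusted p = 9e-08). DNA replication (14 of 37 lower, median -0.3, adjusted p = 4e-09), cholesterol synthesis (10 of 24 lower, PMVK higher, median -0.13, adjusted p = 0.001) and matrix genes (11 of 30 lower, median -0.27, adjusted p = 4.4e-06) followed, with HMGCS1 at -0.89 ± 0.06. The p53 list (6 of 33 higher, FAS and PLK2 lower, median 0.13, adjusted p = 0.0026) and NRF2 targets (7 of 25 higher, median 0.13, adjusted p = 2e-05) were higher, and so were ACO1 at 1.99 ± 0.08 and CBS at 1.51 ± 0.12. PMVK lost its call without DKO MPS1i replicate 1 (0.43) and PLK2 without MAVS MPS1i replicate 2 (-0.17). Adjusted over the list alone, 48 interferon, 24 NF-kB, 17 nucleic acid, 5 interferon and chemokine, 20 DNA replication, 13 matrix and 8 NRF2 members differed in the directions given. In all 2043 genes differed, 893 higher and 1150 lower.

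**Figure D3:**
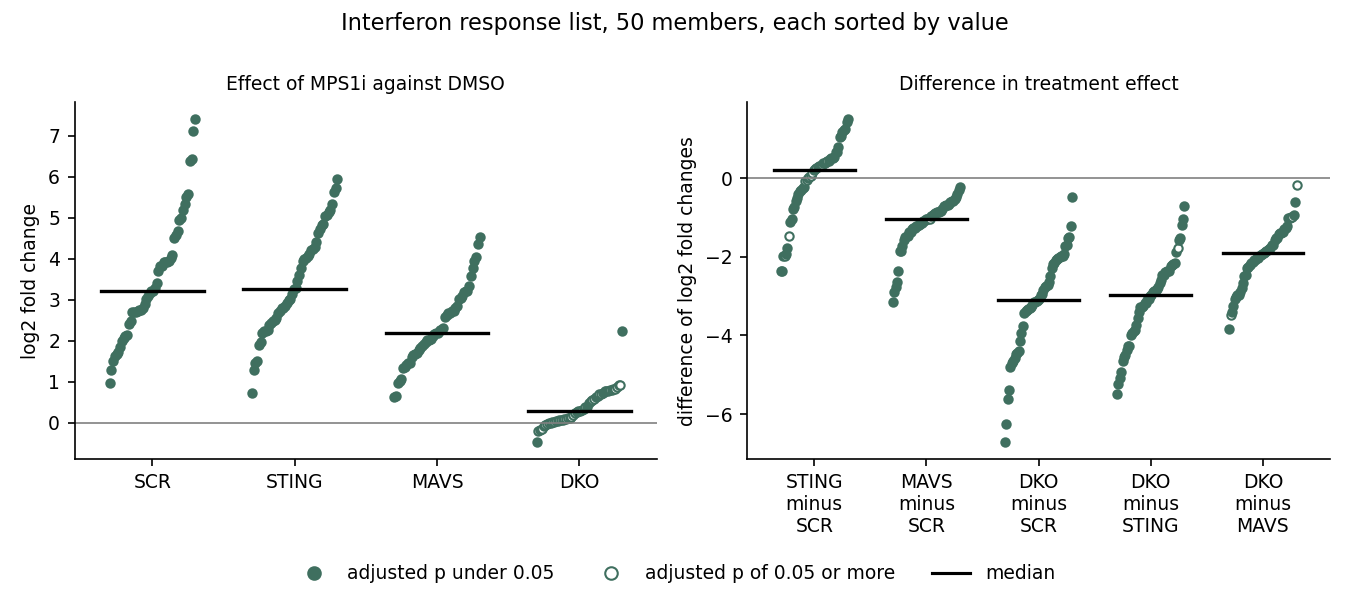
Log2 fold change of each of the 50 interferon list members in the 4 treatment effects and the 5 differences between treatment effects; filled points have an adjusted p under 0.05, open points do not, and black lines are medians. The median difference from SCR is 0.22 in STING-labelled, -1.03 in MAVS-labelled and -3.09 in DKO-labelled cells.

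Without the inhibitor, the genotypes already differed in their interferon-stimulated genes. The mean log2 CPM of the interferon list under DMSO was 4.93 in SCR, 3.56 in STING-labelled, 5.32 in MAVS-labelled and 2.88 in DKO-labelled cells. In STING-labelled cells 42 of 50 members were lower than in SCR (median -1.19, adjusted p = 5.5e-76), IFIT1 by -2.66 ± 0.11, MX1 by -2.27 ± 0.08 and the ISG15 ligase gene HERC5 by -3.05 ± 0.12. The chemokine gene CCL5 had the largest fall at -3.71 ± 0.1. Nucleic acid sensing was lower with 10 of 23 (median -0.51, or -0.2 with genes at their bound, adjusted p = 1.3e-10), DDX58 at -1.44 ± 0.07. MAVS stood at 0.15 ± 0.05 (adjusted p = 0.034), and its call was lost without SCR DMSO replicate 1 (0.16) or 2 (0.11) and without STING DMSO replicate 1 (0.14) or 2 (0.18), and with no filter on low counts (0.13). ATF4 genes were lower with 13 of 28 (median -0.15, adjusted p = 1e-10), ASNS at -0.57 ± 0.06, and cholesterol genes were higher with 6 of 24 (median 0.12, adjusted p = 0.00071), HMGCS1 at 0.25 ± 0.04. Higher genes included the synaptic calsyntenin gene CLSTN2 at 1.78 ± 0.14, HLA-DRA, an MHC class II gene, at 1.67 ± 0.19, and the integrin gene ITGB3 at 1.54 ± 0.07. For the matrix list 10 of 30 were higher and SNAI2 lower (median 0.12, adjusted p = 0.00025), with MMP2 at 0.89 ± 0.07, and with no filter on low counts the list's adjusted p = 0.068. SNAI2 lost its call without STING DMSO replicate 1 (-0.37). When adjusted over the list alone, 45 interferon, 11 nucleic acid and 17 ATF4 members were lower and 10 cholesterol and 12 matrix members higher. In all 1826 genes differed, and 897 without STING DMSO replicate 1, 921 without STING DMSO replicate 2 and 1015 without SCR DMSO replicate 2.

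MAVS-labelled cells went the other way under DMSO. Of 50 interferon members 33 were higher than in SCR (median 0.34, adjusted p = 2.9e-35), OAS2 by 0.68 ± 0.05, MX1 by 0.61 ± 0.07 and BST2, which tethers virus particles, by 0.51 ± 0.05. Antigen presentation was higher with 8 of 20 (median 0.22, adjusted p = 2.4e-08), HLA-B at 0.58 ± 0.08. Matrix genes were higher with 16 of 30 (median 0.23, adjusted p = 4.8e-10), THBS1 at 0.78 ± 0.06 and MMP2 at 0.79 ± 0.07. Nucleic acid sensing had a median of 0.15 (adjusted p = 1.9e-05) with SAMHD1, which degrades nucleotides, at 0.39 ± 0.06, and ATF4 genes were lower with 12 of 28 (median -0.11, adjusted p = 3.1e-08). HLA-DRA at 1.85 ± 0.18 and the class II chaperone gene CD74 at 1.46 ± 0.18 were among the largest rises, and the receptor gene KIT was lower at -1 ± 0.08. Counts adjusted over the list alone were 45 interferon, 12 antigen presentation, 10 nucleic acid and 18 matrix members higher. In all 1177 genes differed, and 339 without MAVS DMSO replicate 1, 457 without SCR DMSO replicate 2, 730 without MAVS DMSO replicate 2 and 744 without SCR DMSO replicate 1.

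DKO-labelled cells also had lower interferon-stimulated genes than SCR under DMSO. Of 50 members 46 were lower than in SCR (median -1.79, adjusted p = 1.9e-45), IFI27 by -4.67 ± 0.12, MX1 by -3.91 ± 0.09 and IFIT1 by -3.79 ± 0.12, and TRIM22 was higher. Nucleic acid sensing was lower with 10 of 23 and higher with 5 (median -0.46, adjusted p = 3e-04), namely ENPP1, IKBKE, RNF135, MAVS and CGAS. The CGAS call (0.21 ± 0.08) was lost without DKO DMSO replicate 1 (0.18) or 2 (0.22) and without SCR DMSO replicate 1 (0.09), with DESeq2 (0.2), with RLE size factors (0.2) and with only the compared groups (0.22). ATF4 genes were lower with 17 of 28, DDIT4 and CHAC1 higher (median -0.34, adjusted p = 2.8e-10), ASNS at -1.48 ± 0.06. Matrix genes were higher with 19 of 30 (median 0.63, adjusted p = 5.7e-14), THBS1 by 2.17 ± 0.06 and FN1 by 1.82 ± 0.05, and PLAUR, TGFBR1 and SKIL were lower. The stromal marker DCN, a matrix proteoglycan gene, was higher by 1.03 ± 0.09, and the endothelial marker PECAM1 stood at 0.88 ± 0.26 (adjusted p = 0.0095, or 0.098 without DKO DMSO replicate 2 and 0.2 without SCR DMSO replicate 1). DNA replication (18 of 37 higher, median 0.19, adjusted p = 1.4e-05), MCM4 at 0.48 ± 0.04, and p53 targets (10 of 33 higher, median 0.15, adjusted p = 0.01), ZMAT3 at 0.85 ± 0.05, were also higher, while the p53 targets TNFRSF10B, at -0.53 ± 0.04, MDM2 and PPM1D were lower. Other calls against a list were lost without 1 library, TRIM22 (0.16), IKBKE (0.37) and TGFBR1 (-0.16) without SCR DMSO replicate 2, CHAC1 (0.32) and PPM1D (-0.19) without DKO DMSO replicate 1 and PLAUR (-0.08) without DKO DMSO replicate 2. HLA-DRA at 2.59 ± 0.17, the collagen receptor gene MRC2 at 2.81 ± 0.15 and the integrin gene ITGA4 at 2.71 ± 0.22 were among the largest rises. IL6 was higher by 1.65 ± 0.07, the opposite of the interferon genes. Antigen presentation had a median of -0.1 (adjusted p = 0.052). Members adjusted over the list alone came to 18 ATF4 genes lower and 20 matrix genes higher, with the other counts the same. In all 5591 genes differed, 2837 higher and 2754 lower.

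After MPS1i all 3 knockout-labelled lines stood below SCR for interferon-stimulated genes. The interferon list was lower with all 50 members in STING-labelled cells (median -1.22, adjusted p = 6.4e-62), with 48 in MAVS-labelled cells (median -0.64, adjusted p = 1.7e-70), where IFI6 and EIF2AK2 did not pass, and with all 50 in DKO-labelled cells (median -4.62, adjusted p = 2e-61). IFIT1 was at -1.62 ± 0.08, -1.12 ± 0.08 and -8.25 ± 0.13 in this order, and MX1 at -1.02 ± 0.07, -0.61 ± 0.06 and -7.02 ± 0.09. Interferon and chemokine genes were lower with 9, 9 and 11 of 11 (medians -3.36, -2.59 and -8.42, the last -6.42 with genes at their bound, adjusted p = 2.2e-13, 3.8e-21 and 9.9e-10). CXCL10 was at -4.79 ± 0.18 in STING-labelled and -2.92 ± 0.15 in MAVS-labelled cells, and IFNB1 at -4.61 ± 0.44 in MAVS-labelled cells. In DKO-labelled cells, IFNL1 was at least 107.3-fold, IFNL2 at least 148.3-fold and IFNB1 at least 42.33-fold lower than in SCR. IFNL2 and IFNL3 are nearly identical and may share reads. All 20 antigen presentation members were lower in each line (medians -1.36, -0.68 and -2.17, adjusted p = 5.3e-28, 6.9e-31 and 3.3e-24), HLA-B at -2.37 ± 0.06, -0.75 ± 0.06 and -3.44 ± 0.07. NF-kB was lower with 21, 14 and 24 of 26 (medians -0.72, -0.31 and -1.13, adjusted p = 1.2e-16, 5.3e-12 and 8.5e-16), and IL1B was higher in DKO-labelled cells. CCL5 was lower by -4.43 ± 0.07, -0.58 ± 0.05 and -6.42 ± 0.08.

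Other genes set the lines apart from SCR after MPS1i. Nucleic acid sensing was lower with 18, 15 and 19 of 23 members (medians -0.76, -0.47 and -2.06, adjusted p = 2.8e-11, 5.3e-12 and 4.6e-13), and MAVS was higher in all 3 lines and RNF135 in STING-labelled cells. DNA replication was lower in STING-labelled (19 of 37, median -0.22, adjusted p = 8.6e-06) and DKO-labelled cells (15 of 37, median -0.2, adjusted p = 0.01), CDC6 at -0.59 ± 0.06 and -0.53 ± 0.06, while GINS4 was higher in both lines and 3 members, among them TYMS at 0.41 ± 0.05, in DKO-labelled cells. NRF2 targets were higher in STING-labelled cells (10 of 25, with GPX2, ABCC2 and CBR1 lower, median 0.11, adjusted p = 0.012), SLC7A11 at 0.68 ± 0.05, and p53 targets in DKO-labelled cells (18 of 33, median 0.34, adjusted p = 0.00012), ZMAT3 at 2.32 ± 0.06, with FAS at -0.69 ± 0.05, MDM2, TNFRSF10B, BBC3 and AEN lower. In STING-labelled cells the calls of RNF135 (0.25, without STING MPS1i replicate 2) and GINS4 (0.25, without SCR MPS1i replicate 2) were lost, and in DKO-labelled cells those of BBC3 (-0.33, without DKO MPS1i replicate 1) and AEN (-0.18, without DKO MPS1i replicate 2). ACO1 was higher by 2.03 ± 0.06 in STING-labelled and 3.27 ± 0.06 in DKO-labelled cells, and CLSTN2 by 2.84 ± 0.14 and 3.37 ± 0.14. In MAVS-labelled cells MRC2 was higher by 1.49 ± 0.16. Adjusted over the list alone, 49 interferon, 16 NF-kB and 16 nucleic acid members were lower in MAVS-labelled cells, 22 DNA replication members lower and 12 NRF2 members higher in STING-labelled cells, and 20 nucleic acid members lower and 19 p53 members higher in DKO-labelled cells. The numbers of differing genes were 5949 in STING-labelled, 2859 in MAVS-labelled and 8087 in DKO-labelled cells. The MAVS number was 1794 without MAVS MPS1i replicate 2, 1855 without MAVS MPS1i replicate 1 and 1801 without SCR MPS1i replicate 2.

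**Figure D4:**
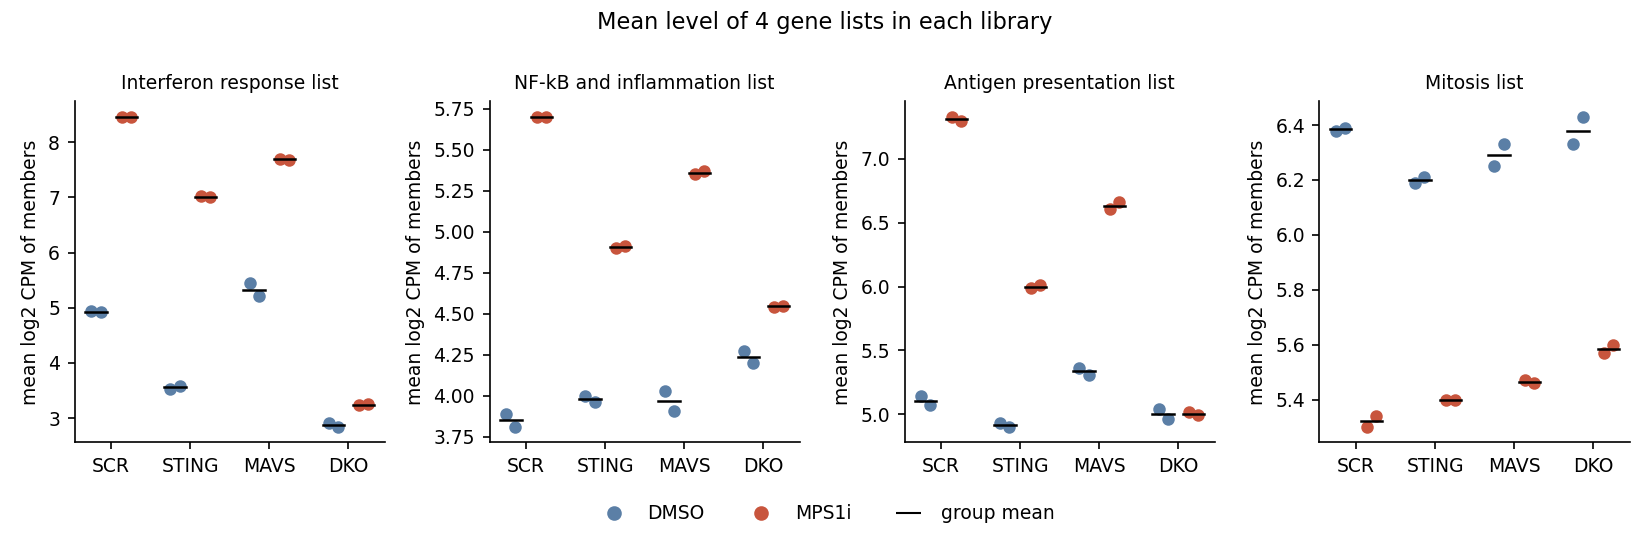
Mean log2 CPM of the members of the interferon, NF-kB, antigen presentation and mitosis lists in each of the 16 libraries, by genotype and treatment. The interferon group means go from 4.93 to 8.46 in SCR, 3.56 to 7.02 in STING-labelled, 5.32 to 7.69 in MAVS-labelled and 2.88 to 3.24 in DKO-labelled cells.

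For several lists the call rested on the setting, so no direction is claimed for them. Lung epithelium genes had medians of 0.3, 0.19 and 0.12 after MPS1i in SCR, STING-labelled and MAVS-labelled cells (adjusted p = 0.044, 0.046 and 0.043), with adjusted p = 0.17, 0.15 and 0.14 with an estimated correlation, and 0.11 in DKO-labelled cells (adjusted p = 0.13). NRF2 targets had a median of -0.06 in SCR (adjusted p = 0.049, and adjusted p = 0.075 with an estimated correlation) and of -0.04 in DKO-labelled cells (adjusted p = 0.019, or 0.081 with the filter of 1 CPM and 0.051 in a fit of the DKO libraries alone). Mitosis genes had median differences in treatment effect of 0.26 and 0.24 between STING-labelled or DKO-labelled cells and SCR (adjusted p = 2e-07 and 9.9e-06), with adjusted p = 0.13 and 0.16 with an estimated correlation. Replication histones had differences from SCR of 0.47, 0.36 and 0.65 in STING-labelled, MAVS-labelled and DKO-labelled cells, with adjusted p = 0.16, 0.15 and 0.16 with an estimated correlation. Under DMSO, NF-kB genes had medians of 0.08, 0.1 and 0.27 against SCR in the same order, with adjusted p = 0.13, 0.18 and 0.084 with an estimated correlation. Antigen presentation (-0.21) and mitosis (-0.19) in STING-labelled cells under DMSO had adjusted p = 0.058 and 0.052 with an estimated correlation, and matrix genes in DKO-labelled cells after MPS1i (0.41) had adjusted p = 0.075. Stromal and endothelial genes under DMSO had medians of 0.56 in MAVS-labelled and 0.54 in DKO-labelled cells (adjusted p = 0.016 and 0.047), with adjusted p = 0.11 and 0.14 with an estimated correlation.

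Cholesterol synthesis went both ways after MPS1i in SCR (10 of 24 up, 5 down, median 0.02, adjusted p = 0.37), where HMGCS1 rose by 1.1 ± 0.04 and EBP fell by 0.93 ± 0.07, and was not called in STING-labelled (median -0.04, adjusted p = 0.93) or MAVS-labelled cells (median 0.06, adjusted p = 0.66). The p53 list was not called in SCR (9 of 33 up, 8 down, adjusted p = 0.91), where PLK2 rose by 1.06 ± 0.05 and ZMAT3 fell by 1.31 ± 0.06. Its median was 0.03 while the test's direction was down, and CDKN1A, the p53 target that stops the cell cycle, stood at 0.13 ± 0.11 (adjusted p = 0.35). Lysosome genes had medians of 0.02, 0.11, -0.06 and 0 in SCR, STING-labelled, MAVS-labelled and DKO-labelled cells (adjusted p = 0.91, 0.11, 0.29 and 0.51), and CTSL, a protease gene, rose in SCR by 0.79 ± 0.05. Of the markers of other cell types, 6 of 18 immune and 4 of 14 stromal and endothelial genes were abundant enough to test, and neither list was called after MPS1i. Their medians were 0.95, 0.65, 0.99 and 0.48 for immune genes (adjusted p = 0.14, 0.076, 0.1 and 0.12) and 0.75, 0.63, 0.47 and 0.14 for stromal genes (adjusted p = 0.18, 0.076, 0.2 and 0.44). In the 15 comparisons, the other lists whose median and test differed in sign were uncalled, namely NRF2 targets in STING-labelled cells under DMSO, lung epithelium in MAVS-labelled and DKO-labelled cells under DMSO, and immune genes in STING-labelled cells under DMSO and in the differences of STING-labelled and MAVS-labelled cells from SCR and of DKO-labelled from MAVS-labelled cells.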

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

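Of the tests below, only those on members with at least 5 CPM and on a ceiling in SCR were written before their result was seen. All others were chosen only after the result was seen. Each item is here because the treatment effect differed between genotypes in a direct test of the difference, or because genes were called in opposite directions in 2 genotypes. The numbers of genes called in opposite directions do not require that the difference was called too. The interferon list difference of STING-labelled cells from SCR was not called and is given beside that of MAVS-labelled cells.

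The interferon list rose far less after MPS1i in DKO-labelled cells than in SCR (median difference -3.09), STING-labelled (-2.98) or MAVS-labelled cells (-1.91). Mitosis genes fell in DKO-labelled cells too (median -0.86), which argues against an inactive dose or untreated libraries under a wrong label, and the difference from SCR was -2.98 with all libraries thinned to equal depth, which argues against depth. What stays open is another property of the 1 DKO-labelled line, whose interferon genes were already lower under DMSO (median -1.79), and this cannot be told apart from the loss of STING and MAVS. The design names the double knockout as a biological explanation, and a shared need for STING or MAVS may account for the loss.

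In STING-labelled cells the interferon list rose from a lower start with a median difference of 0.22 from SCR, with 20 members higher and 16 lower, and in MAVS-labelled cells it rose less than in SCR (median difference -1.03). Low counts under DMSO could inflate folds, but the 30 members with at least 5 CPM in every DMSO library had a median difference of 0.24 (bootstrap interval -0.24 to 0.41), and the 25 members with the higher mean levels had 0.38 (0 to 0.52), against -0.06 for the other 25. That second split was added because the first selects members by their minimum. Its mean covers all 16 libraries, MPS1i included, so it does not sort members by their DMSO counts. It is also not separate from the split by SCR level below. Members are not independent, which limits both intervals. A ceiling on strongly expressed members in SCR after MPS1i is a candidate explanation. Members with a higher SCR level had a larger difference (Spearman 0.31, permutation p = 0.028, medians of -0.31, 0.23 and 0.38 for members split in 3 from low to high SCR level), only just past the limit of 0.3 set for it, with members that are not independent.

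Genes called in opposite directions were few beside those called the same way. Between STING-labelled and SCR cells, 1316 opposite calls would be expected after MPS1i if calls in the 2 genotypes were independent. There were 136, against 2209 up and 1832 down in both. They include 11 copies of the U2 small nuclear RNA with the same values, and genes such as the mucin gene MUC16 at -0.77 and 0.91, and 57 without STING DMSO replicate 2, 80 without STING MPS1i replicate 1, 73 without STING MPS1i replicate 2 and 83 with DESeq2. Between DKO-labelled and SCR cells there were 202 (864 up and 1025 down in both), such as PMEPA1, an inhibitor of TGF-beta signalling, at 0.65 and -0.69, and 115 without DKO MPS1i replicate 1 and 125 without DKO MPS1i replicate 2. Between DKO-labelled and MAVS-labelled cells there were 83 (790 up and 989 down in both), such as the scavenger receptor gene OLR1 at -0.96 and 0.8, and 142 without DKO DMSO replicate 1, 42 without DKO MPS1i replicate 1, 52 without DKO MPS1i replicate 2 and 53 without MAVS DMSO replicate 1. Between DKO-labelled and STING-labelled cells there were 45 (840 up and 1001 down in both), such as TRIM69 at -0.45 and 1.49, and 24 without DKO MPS1i replicate 1, 26 without DKO MPS1i replicate 2 and 29 without STING MPS1i replicate 1. Between MAVS-labelled and SCR cells there were 12 (2734 up and 2651 down in both), such as the transcription factor gene ONECUT2 at 0.17 and -0.23, and 4 without MAVS DMSO replicate 2.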

How the results depend on the processing

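In the 7 comparisons below, the number of called genes moved by over 1.5 times without at least 1 of the libraries, and by less with DESeq2 or another normalization. For the treatment effect in DKO (2648 genes), 1433 were called without DKO MPS1i replicate 1 and 3120 without DKO DMSO replicate 1, and 1629 with only the compared groups. The treatment effect in STING (5269 genes) became 3364 without STING MPS1i replicate 2 and 4202 without STING MPS1i replicate 1. The difference in treatment effect DKO vs STING (848) ranged from 535 without DKO MPS1i replicate 1 to 1107 without DKO DMSO replicate 2, and that of MAVS vs SCR (1336) from 851 without MAVS DMSO replicate 1 to 1066 without SCR DMSO replicate 1.

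The genotype effect of MAVS in DMSO (1177) moved most, from 339 without MAVS DMSO replicate 1 to 744 without SCR DMSO replicate 1. The genotype effect of MAVS in MPS1i (2859) ranged from 1794 without MAVS MPS1i replicate 2 to 1991 without SCR MPS1i replicate 1, and the genotype effect of STING in DMSO (1826) from 897 without STING DMSO replicate 1 to 1375 without SCR DMSO replicate 1. Fewer libraries give less power, so lower numbers are in part a matter of size.

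The interferon list difference STING vs SCR (0.22, not called) was called upward with no low-count filter (0.23, adjusted p = 0.025) and without STING DMSO replicate 2 (0.24, adjusted p = 0.04), and its median lay between 0.17 without STING MPS1i replicate 1 and 0.25 without SCR DMSO replicate 2. The interferon list in DKO (0.29) had adjusted p = 0.14 with an estimated correlation, at the same median of 0.29. For these 2 lists the cause was not tested. GRIP2, difference in treatment effect STING vs SCR, turned from -4.41 to 0.18 without STING DMSO replicate 2 (adjusted p = 0.85) and was -7.66 without SCR DMSO replicate 1, so it is not named in the report. Of 14974 alternatives for named genes, 14352 had the same call and 1 was reversed. Most named genes were chosen by size or adjusted p in the main fit, so this share does not describe calls in general. Of 3385 for lists, 3146 had the same call. Depth limits values near 0, such as IFNB1 with at most 19 counts in each library outside SCR MPS1i, and nucleic acid sensing in STING-labelled cells, whose median of 1.29 is 0.67 with genes at their bound.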

Other observations

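MHC class II genes, which present peptides to CD4 T cells, were higher in all 3 knockout-labelled lines than in SCR under DMSO. HLA-DRA stood at 1.29 ± 0.1 CPM (SD, n = 2) in SCR, 4.09 ± 0.27 in STING-labelled, 4.58 ± 0.45 in MAVS-labelled and 7.71 ± 0.25 in DKO-labelled cells. The invariant chain gene CD74 stood at 1.57 ± 0.22, 3.19 ± 0.034, 4.37 ± 0.15 and 6.11 ± 0.23 CPM in the same order. Of 9 class II genes tested, 6, 6 and 9 were higher (medians 1.18, 1.4 and 2.09). After MPS1i the medians against SCR were 0.42, 0.56 and 1.24, with 1, 3 and 7 genes higher. The list was chosen after its values were seen, and the 3 comparisons share the SCR libraries.

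More genes were detected after MPS1i in each genotype with libraries thinned to equal depth. The numbers went from 22278 ± 59 to 24159 ± 117 in SCR, from 22568 ± 377 to 23452 ± 47 in STING-labelled, from 22244 ± 353 to 23926 ± 32 in MAVS-labelled and from 22262 ± 199 to 23306 ± 129 in DKO-labelled cells (SD, n = 2). The mean rise was 1373 genes, with an exact permutation p = 0.0015 within genotypes, the smallest that the 1296 arrangements can give.

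All tests in the paragraphs below were chosen only after the result was seen. For the class II genes, chance values of the shared SCR DMSO libraries are argued against for DKO-labelled cells by the median of 1.24 against SCR after MPS1i, which uses other libraries. For the STING-labelled and MAVS-labelled lines this stays open, as their lower median was 0.42 and few of the genes were called after MPS1i. Class II genes also rose in SCR with MPS1i (median 0.48, 4 of 9 called), which lowers these differences whatever their cause. HLA-DRA stood after MPS1i at 1.69 ± 0.23 CPM in SCR, 3.3 ± 0.51 in STING-labelled and 4.39 ± 0.18 in MAVS-labelled cells. Immune cell RNA is argued against by the summed level of the 17 genes of the immune list other than CD68, which was 2.33 ± 0.028 CPM in SCR and 2.12 ± 0.36 in DKO-labelled cells under DMSO, a change of -0.22, while class II genes went from 8.44 ± 0.21 to 31.2 ± 0.91 CPM. CD68, left out after its values were seen, stood at 75.05 CPM in SCR under DMSO, far above the other 17, and goes the other way, higher in DKO-labelled cells by 0.55 ± 0.07 (adjusted p = 5.4e-06). That test was specified again 2 times after its values were seen. Outgrowth of a subpopulation while the lines were made (median 2.09 under DMSO) cannot be told apart from an effect of the knockouts, with 1 line per genotype.

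The loss of the interferon response in DKO-labelled cells was compared with the sum of the losses in the single lines on the log2 scale. The list fell further than the sum (median -1.87, adjusted p = 5.1e-126, and adjusted p = 7.3e-05 with an estimated correlation), with 41 of 50 members lower. The nucleic acid sensing list had a median of -0.53 with 8 members lower. In all 164 genes departed from the sum, 36 higher and 128 lower. The departure is from a sum on the log2 scale alone. Signals of STING and MAVS that add in CPM would also depart from a sum of log2 losses. That each may replace part of the other is a hypothesis found and tested on the same data, and this comparison does not decide it.

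MPS1 inhibition missegregates chromosomes, and a shared gain or loss of a chromosome in the MPS1i libraries would move the genes of that chromosome together. Across 23 chromosomes and 4 treatment effects the largest median shift was 0.1 on the log2 scale, which argues against a shared change but says nothing of changes that differ from cell to cell.

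ACO1 lies 533 bases from DDX58 and is transcribed towards it. It went from 92.3 ± 2.7 to 14.4 ± 0.56 CPM in SCR, from 131 to 58.9 in STING-labelled, from 101 to 24.5 in MAVS-labelled and from 145 to 139 CPM in DKO-labelled cells. DDX58 rose by 3.43, 3.46 and 2.29 on the log2 scale in the first 3 and did not pass the test in DKO-labelled cells with all libraries, so the fall of ACO1 did not follow the fold of DDX58. DDX58 levels after MPS1i were 1280, 479, 722 and 40.1 CPM, the reverse order of ACO1 levels. Strong transcription of a gene could lower its convergent neighbour in general. The 56 neighbours within 5 kb of genes that rose at least 4-fold in SCR had a median of 0.02 (bootstrap interval -0.12 to 0.21). Of them, 16 were higher, 12 lower and 28 not called, which argues against a general effect of a large fold. These neighbours were chosen by fold, and some lie beside scarce genes such as SLC15A3 (mean 2.3 CPM). An effect of a high level of transcription was therefore not tested. For ACO1 itself no test decides.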
